A study of Homo sapiens with 12 samples.

How the data were processed

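The 12 samples are 3 groups of 4, and the labels number them as replicate 1 and parts 2-1, 2-2 and 2-3 of replicate 2, each part holding a subset of the RNAs. Per the labels, a pool of in vitro transcribed constructs of 125 nt was treated with 10 mM 1M7 at 37 °C for 75 s after folding. Controls took DMSO in place of the reagent, and a denatured sample was treated at 95 °C for 1 min in 50% formamide. Mutation rates were turned into reactivities, and these were used to model secondary structure, per the labels. Bowtie2 and the genome build hg38 are named in the submitters' processing notes without version or role. The mutation caller, depth filter, folding program and the way replicates were combined are not given in the sources used here.

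The reactivity is a score without a fixed unit, deposited by the authors as 1 value per RNA and construct position for the whole series. Of 60045 values none is below 0, 23.4% are exactly 0, and the highest is 21.1. In 480 of 481 RNAs the 90th percentile of the RNA's own values is 1 within 0.001, so each RNA was scaled to itself and levels can be set against each other within an RNA but not as absolute levels between RNAs. How the DMSO and denatured rates entered the values is not stated, and they are not used here on their own. The read depth is unknown, so no interval for counting error is given, and Wilson intervals of shares cover the number of RNAs or nucleotides only. The deposited structures give a number for each position, read here as the position of its pairing partner, with 0 for unpaired. All 476 structured RNAs have 125 values, and mir-873 and mir-941-4 have reactivity but no structure in the table.

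From these tables pairs were grouped into unbranched runs, each from a hairpin loop outward with bulges and internal loops allowed and a multiloop as its end. The run with the most pairs is the main hairpin. Positions were classed as apical loop, internal loop (unpaired on both strands), bulge (unpaired on 1 strand), stem pair, or flank (unpaired outside the outermost pair of the main stem). Reactivity was averaged over the nucleotides of a class within each RNA, so that the RNA is the unit of the tests, apart from profile similarity, which uses pairs of RNAs and shuffles names among RNAs. Paired comparisons used two-sided sign-flip permutation tests of the differences per RNA with 100000 resamples. Lists were compared with all other RNAs by two-sided permutation of the RNA labels with 100000 resamples, or exactly where a list has 3 members, on stem pairs, apical loop size, unpaired share of the stem and mean reactivity of the hairpin. Sets of related tests were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Segments of the stem were computed for stems of at least 9 pairs, and helix ends and interiors for RNAs with at least 2 nucleotides of each. Positions of genes were taken from the RefSeq annotation of GRCh38.p14 by gene symbol for 475 of 476 RNAs, of which 388 lie within the span of another gene. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

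The tests, the lists and their members, the alternatives and the rule for named RNAs were fixed before the data were examined, except where a sentence says otherwise. The rule names 24 well-studied pri-miRNAs where analysed, in each main comparison the 5 RNAs with the highest and the 5 with the lowest value (ties by name), and of each list the members with the highest and lowest value. The code was tested on hand-made structures, of which 14 of 14 checks passed, on simulated reactivities over the 476 real structures, and on random numbers. A simulated difference of 0.5 between unpaired and paired nucleotides came back as 0.502. The other checks used random numbers drawn without structures or reactivities, and fewer resamples. With no difference built in, 5 of 100 sets gave p at or below 0.05 in the sign-flip test and 5 of 100 in the list test with 8 RNAs. Lists of 40 RNAs shifted by a full SD were found in 100 of 100 sets, and smaller shifts were not tried.

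Alternatives changed the summary per RNA, capped values at 0 and 2, left out 10 nucleotides at each end, counted each family once, took the hairpin that holds position 63, removed isolated pairs, or changed the segments of the stem to the lowest and uppermost 11 pairs. Added after the tables had been seen were leaving out nucleotides at exactly 0, ending the stem at the first internal loop with at least 4 unpaired nucleotides on both strands, leaving out let-7a-1, opening helices of fewer than 4, 5 or 6 stacked pairs next to the apical loop, and profile similarity in the family lists alone. The hairpin that holds position 63 and the removal of isolated pairs were planned for the architecture, stem segments, arms and lists, and were added later for the reactivity comparisons, correlations, arm windows and let-7 loop. The median, the caps and leaving out ends were added later for arm reactivity, and leaving out ends for the area under the curve. Planned work that needs the sequence was not run: folding from sequence alone and its agreement with the deposited structures, reactivity by base, pair types, motifs at the hairpin ends, and the window at the mature let-7 end. Agreement between replicates was not computed, because the tables hold no value per replicate. Precursors reported to bypass Drosha or Dicer (mir-320a, mir-484, mir-877, mir-1224, mir-1226 and mir-451a) and the well-studied mir-20a are not analysed here.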

Results

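Primary microRNA transcripts (pri-miRNAs) hold a hairpin that the nuclease Drosha cuts to release the precursor microRNA. The study probed the structure of human pri-miRNAs in solution with SHAPE-MaP. In this assay the reagent 1M7 acylates flexible nucleotides on the ribose hydroxyl, and reverse transcriptase reads the adduct as a mutation. The RNAs were made by in vitro transcription as constructs of 125 nt with the hairpin in the middle, and were probed as a pool. The 12 samples fall into 3 groups of 4: folded RNA with 1M7, folded RNA with the solvent DMSO, and denatured RNA with 1M7. Reactivity was analysed for 478 of the 519 pri-miRNAs the series names and for 3 control RNAs, and pairing for 476 pri-miRNAs. The tables give 1 reactivity per nucleotide for the whole series, so no value carries a replicate error. How the DMSO and denatured samples entered the values is not stated, and the read depth is unknown. Each SD below is the spread between RNAs, n is a number of RNAs, and the p-values measure that spread alone.

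Unpaired nucleotides reacted more than paired ones in each of the 476 pri-miRNAs. Mean reactivity was 0.705 ± 0.120 (SD, n = 476) for unpaired and 0.182 ± 0.0622 for paired nucleotides, a 3.87-fold ratio of means. The difference of 0.523 ± 0.152 had p = 1e-05 in a two-sided sign-flip permutation test, the smallest p that the 100000 resamples can give. It was widest in let-7a-1 (1.04), let-7f-2 (0.909), mir-3173 (0.871), mir-132 (0.862) and mir-219a-1 (0.856). It was narrowest in mir-3180-3 (0.0728), mir-6720 (0.0732), mir-210 (0.0888), mir-325 (0.0929) and mir-1269a (0.120). The liver microRNA transcript mir-122 had 0.678 for unpaired and 0.102 for paired nucleotides, and the transcript of the oncogenic microRNA mir-21 had 0.645 and 0.151. Among the 24 well-studied pri-miRNAs the lowest paired means were those of mir-142 (0.0770) and mir-223 (0.0782), both microRNAs of blood cells, and the highest was that of mir-92a-1 (0.249). Of all paired nucleotides 3.38% (Wilson 95% interval 3.20 to 3.56) lay above 0.85, against 31.5% (30.9 to 32.1) of the unpaired. Below 0.1 lay 16.9% (16.4 to 17.4) of the unpaired nucleotides. These intervals treat nucleotides as independent, although they lie side by side within 476 RNAs that are each scaled to themselves, so they are too narrow as a measure of precision. The structures were modelled by the submitters with these same reactivities, so the difference describes the models and is not independent evidence for them. The same holds for the reactivity comparisons below between parts, arms and strands.

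Reactivity differed between the parts of the main hairpin and its flanks. The main hairpin is the unbranched stem with the most pairs and its apical loop. Flanks hold all unpaired nucleotides outside the main stem. They therefore include multiloop nucleotides and the loops of other hairpins, which were present in 228 of 476 RNAs. Apical loops were the most reactive part, at 1.04 ± 0.392 (SD, n = 476). Bulges, where only 1 strand has unpaired nucleotides, followed at 0.865 ± 0.524 (n = 390). The 5′ flank had 0.596 ± 0.332 (n = 378), internal loops 0.545 ± 0.233 (n = 474), the 3′ flank 0.454 ± 0.289 (n = 453) and stem pairs 0.176 ± 0.0672 (n = 476). Apical loops exceeded internal loops in 411 of 474 RNAs and bulges in 260 of 390. Bulges exceeded internal loops in 276 of 389 RNAs, with means of 0.866 and 0.549. All 15 pairs of parts differed at an adjusted p of 0.00237 or less in two-sided sign-flip permutation tests with Benjamini-Hochberg adjustment. The parts were read from models made with these reactivities, so the differences describe the models. The order of internal loops and 3′ flank was not stable. Their difference went from 0.0915 to -0.151 with the 10 nucleotides at each end left out, and to -0.00922 (permutation, adjusted p = 0.618) with the stem ended at a large internal loop. The other differences with flanks kept their direction with the ends left out. Internal loops minus 5′ flank went from -0.0674 to -0.278, bulges minus 5′ flank from 0.295 to 0.135, bulges minus 3′ flank from 0.438 to 0.238, and 3′ flank minus stem pairs from 0.278 to 0.482. Apical loops minus 5′ flank went from 0.446 to 0.263, and minus 3′ flank from 0.576 to 0.376.

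**Figure D1:**
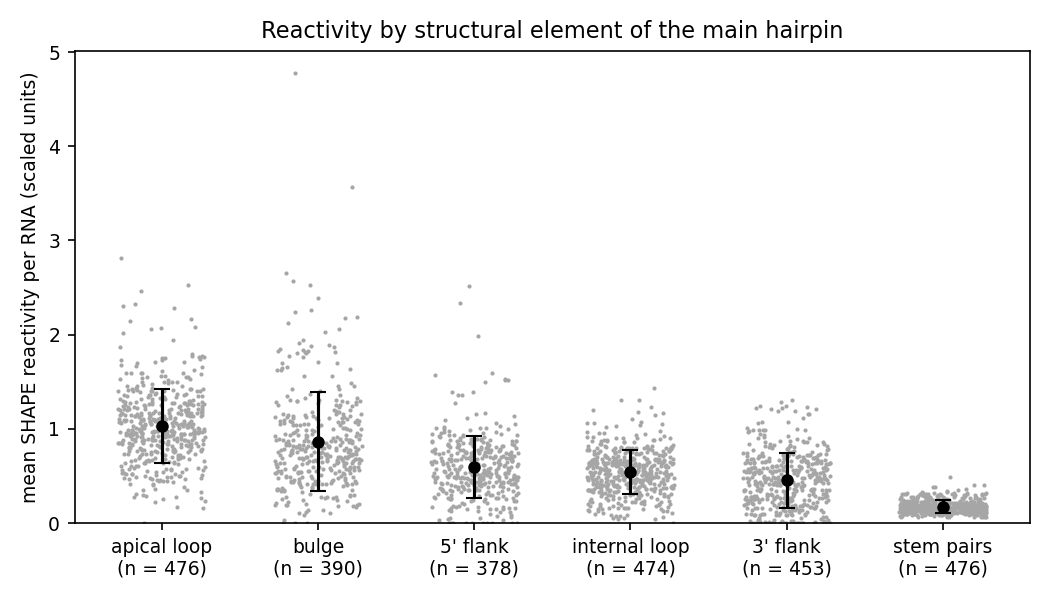
Mean SHAPE reactivity per RNA (vertical axis, scaled units) in the parts of the main hairpin and in its flanks (horizontal axis). Grey points are RNAs, and black points with bars are the mean ± SD over RNAs. Apical loops average 1.04, bulges 0.865 and stem pairs 0.176.

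Each RNA is scaled to its own 90th percentile, so values of different RNAs are levels relative to the rest of the same RNA. On that relative scale the highest apical loops were those of mir-3173 (2.81), mir-132 (2.53), mir-106a (2.46), mir-507 (2.33) and mir-374a (2.30). The lowest were those of mir-210 (0), mir-196b (0.166), mir-3180-3 (0.170), mir-151a (0.222) and mir-28 (0.237). Among the well-studied transcripts, mir-375 of pancreatic islets (1.77), mir-200c (1.70), mir-150 (1.60), mir-144 (1.53), mir-31 (1.46) and mir-9-1 (1.40) had the highest apical loop reactivity. The lowest were mir-155 (0.519), let-7a-1 (0.541), let-7g (0.576) and mir-19b-1 (0.682). In mir-2116 the internal loops (1.43) exceeded the apical loop (0.539) by the widest margin, and mir-151a, mir-302c, mir-3194 and let-7a-3 came next. The margin in the other direction was widest in mir-3173, mir-132, mir-106a, mir-514b and mir-2278.

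Pairs at helix ends, next to an unpaired nucleotide or a break in the helix, reacted more than pairs stacked on both sides. Their means were 0.249 ± 0.0791 and 0.139 ± 0.0666 (SD, n = 476), and helix ends were higher in 450 RNAs and lower in 26. The p of the two-sided sign-flip permutation test was 1e-05. Ends and interiors were read from models made with these reactivities, so the difference describes the models and is not independent evidence. The difference was widest in mir-3150b (0.328), mir-1269a (0.325), mir-96 (0.317), let-7f-1 (0.315) and mir-3611 (0.313). It had the opposite sign in mir-184 (-0.136), mir-3918 (-0.0894), mir-1180 (-0.0873), mir-1283-2 (-0.0854) and mir-1278 (-0.0720). The tables hold no sequence, so G-C, A-U and G-U pairs were not compared.

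How far reactivity ranks unpaired above paired nucleotides was measured per RNA as the area under the receiver operating curve, a measure added after the tables had been seen. Its median was 0.807, with quartiles of 0.737 and 0.845. The highest values were those of let-7f-2 (0.952), mir-584 (0.941), mir-516b-2 (0.925), mir-10b (0.921) and mir-410 (0.921). The lowest were those of mir-210 (0.457), a hypoxia-induced microRNA, mir-5094 (0.508), mir-4662a (0.525), mir-513a-2 (0.545) and mir-1269a (0.547). The 24 well-studied transcripts spanned 0.718 for mir-144 to 0.921 for mir-10b. In 304 of 476 RNAs no other RNA's structure gave a higher value than the RNA's own structure, and in 385 the own structure was among the best 5. Each structure was modelled with the reactivities of its own RNA. The modelling therefore favours the own structure, and these values and ranks are not independent evidence for the models.

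**Figure D2:**
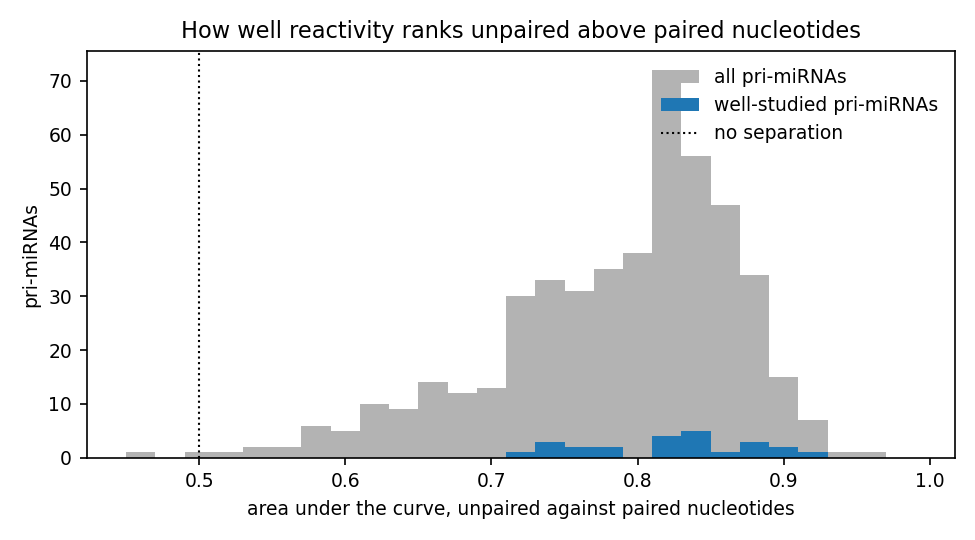
Number of pri-miRNAs (vertical axis) by the area under the curve with which reactivity separates unpaired from paired nucleotides (horizontal axis, no unit); grey bars are all 476 RNAs and blue bars the 24 well-studied ones. The median is 0.807 and mir-210, at 0.457, lies lowest.

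The next question was what the main hairpins look like. The stem had a median of 37 pairs (quartiles 33 and 41, range 3 to 49) and the apical loop a median of 9 nt (quartiles 6 and 12, range 3 to 30). In 301 of 476 RNAs (63.2%, Wilson 95% interval 58.8 to 67.4) the stem held 30 to 40 pairs. A bulge was present in 390 RNAs (81.9%, 78.2 to 85.1) and an internal loop in 474 (99.6%, 98.5 to 99.9). Stems carried 1.98 ± 1.52 bulges and 3.97 ± 1.63 internal loops (SD, n = 476), and 21.3% ± 7.26 of stem nucleotides were unpaired. A further hairpin loop lay elsewhere in the construct in 228 RNAs (47.9%, 43.4 to 52.4), and a multiloop enclosed the main hairpin in 66.

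**Figure D3:**
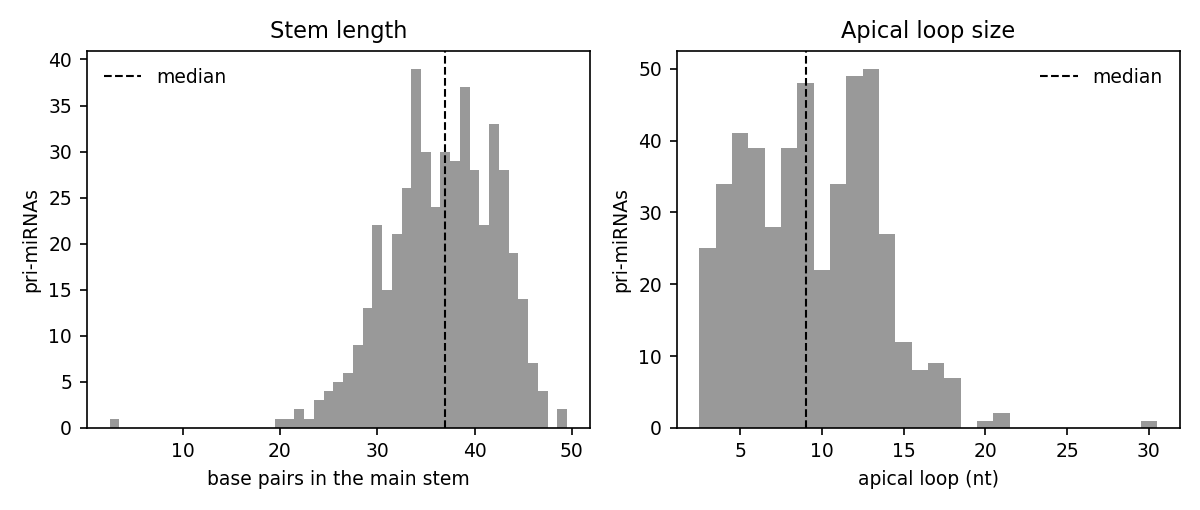
Numbers of pri-miRNAs (vertical axes) by pairs in the main stem (left) and by apical loop size in nt (right); dashed lines are medians. Medians are 37 pairs and 9 nt, and the single stem of 3 pairs is that of let-7a-1.

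The longest stems were those of mir-137, a neuronal microRNA, and mir-580 with 49 pairs, then mir-26b, mir-486-1 and mir-539 with 47. The shortest was that of let-7a-1 with 3, whose apical part is branched in the model, then mir-874 with 20, mir-302c with 21, and mir-3614 and mir-5094 with 22. Among well-studied transcripts, mir-144 and mir-200c had 45 pairs, mir-30a 44, mir-19b-1 and mir-150 43, and mir-122 and mir-223 42. Stems of mir-34a and mir-155 held 40 pairs, those of mir-17, mir-92a-1 and mir-375 39, that of mir-21 38, and those of let-7a-2, let-7g and mir-9-1 36. Shorter stems were found in mir-18a and mir-125b-1 (34), mir-16-1 (33), mir-1-1 and mir-10b (32), mir-142 (31) and mir-31 (29). The largest apical loops were those of mir-4637 (30 nt), let-7a-2 and let-7c (21 nt), mir-218-2 (20 nt) and let-7e (18 nt). The smallest, of 3 nt, were shared by 25 RNAs, among them let-7a-3, let-7f-2, mir-106a, mir-1256 and mir-1283-2. Stems with the highest unpaired share were those of mir-18b (42.1%), mir-532 (40.2%), mir-4664 (39.8%), mir-1913 (39.3%) and mir-5194 (37.6%). After let-7a-1 (0%), the lowest shares were those of mir-4637 (2.94%), mir-1278 (3.23%), mir-3614 (4.35%) and mir-5000 (4.92%).

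Across RNAs, longer stems had a higher unpaired share, with Pearson r = 0.227 (adjusted p = 3e-05) and Spearman rho = 0.232 (adjusted p = 3e-05) in permutation tests over 476 RNAs. Without the 2 RNAs farthest from the median stem, r was 0.2. Longer stems had smaller apical loops, with r = -0.122 (permutation, adjusted p = 0.011) and rho = -0.142 (permutation, adjusted p = 0.00279), and r was -0.146 without the 2 farthest. A further closing pair in a model lengthens the stem and shrinks the loop, so part of this relation may be built in. The permutation does not keep that link, so its p-values do not speak on a relation beyond it. With the stem ended at the first internal loop of at least 4 unpaired nucleotides on both strands, that relation was no longer past the threshold (r = -0.0228, permutation adjusted p = 0.618) and the first rose to r = 0.453. Apical loop size and apical loop reactivity had r = -0.0889 (permutation, adjusted p = 0.0513), rho = -0.0653 (permutation, adjusted p = 0.155) and r = -0.0914 without the 2 farthest. These 3 relations were adjusted together, and were chosen after the tables had been seen.

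The share of unpaired nucleotides was highest in the basal part of the stem. With the pairs of each stem split into a basal, a middle and an apical segment of equal size, 28.6% ± 13.5 (SD, n = 475) of basal, 14.6% ± 9.06 of middle and 15.6% ± 9.32 of apical nucleotides were unpaired. The basal segment exceeded the middle one in 376 RNAs and the apical one in 363, each with adjusted p = 1.5e-05 in sign-flip permutation tests. Middle and apical segments were not told apart by the permutation test (difference -0.975 percentage points, adjusted p = 0.115). The basal excess over the middle was widest in mir-652 (50.9 percentage points), mir-1277 (48.2), mir-200a (48), mir-4766 (48) and mir-2681 (46.2). It had the opposite sign in mir-5581 (-32.5), mir-324 (-26.6), mir-7-2 (-26.4), mir-588 (-21.6) and mir-381 (-21.4). In mir-21 the basal, middle and apical shares were 42.2%, 3.70% and 11.1%, and in mir-155, a microRNA of activated immune cells, 37.8%, 0% and 7.14%. With the stem ended at the first large internal loop, the mean basal excess over the middle was 7.75 percentage points in place of 14.1.

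Counted in nucleotides from the pair that closes the apical loop, and from 2 nt on, the unpaired share had a local minimum, a plateau and a rise. At 15 to 20 nt it averaged 12.2% ± 12.9 (SD, n = 475), at 2 to 9 nt 20.4% ± 15.3 (n = 475), and at 21 to 29 nt 18.6% ± 12.6 (n = 469). Farther down it was 18.1% ± 16.9 at 30 to 34 nt (n = 427) and 50.1% ± 21 at 38 to 44 nt (n = 269). The share at 2 to 9 nt was above that at 15 to 20 nt in 297 RNAs and below it in 138. From 30 to 34 nt to 38 to 44 nt the share was higher by 31.6 percentage points in the 269 RNAs whose stems reach that far, and it rose in 237 of them. Each of the 3 comparisons had adjusted p = 1e-05 in sign-flip permutation tests, with windows chosen after the profile had been seen. At 49 nt the share was lower again, 29.8% on the 5′ arm (n = 235) and 40.3% on the 3′ arm (n = 226). Positions were counted only up to the outermost pair, which is paired by definition. This lowers the share where stems end, so the fall at 49 nt may not be a feature of the stems. Mean reactivity of the 5′ arm was 0.180 at 20 nt and 0.433 at 38 nt, and that of the 3′ arm 0.170 and 0.410.

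The 3′ arm of the stem had more unpaired nucleotides than the 5′ arm, and those of the 5′ arm reacted more. Stems held 9.84 ± 4.55 unpaired nucleotides on the 5′ arm and 11 ± 5.85 on the 3′ arm (SD, n = 476). The 3′ arm had more in 234 RNAs, the 5′ arm in 179 and neither in 63 (two-sided sign-flip permutation test, adjusted p = 2e-05). The 3′ excess was largest in mir-3681, with 20 nt, and mir-3174, with 18 nt, and then in mir-1301, mir-3121 and mir-487a. The 5′ excess was largest in mir-875 (14 nt), mir-412 (13 nt), and mir-204, mir-376c and mir-1283-2 (12 nt each). Unpaired stem nucleotides had a mean reactivity of 0.637 ± 0.310 on the 5′ arm and 0.575 ± 0.296 on the 3′ arm (SD, n = 475), higher on the 5′ arm in 274 RNAs (permutation, adjusted p = 0.00106). Without nucleotides at exactly 0 this second difference was 0.0420 (permutation, adjusted p = 0.0515). With the stem ended at the first large internal loop the first was -0.708 nt in place of -1.14 nt.

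Lists of related pri-miRNAs fixed in advance were compared with all other RNAs, to see which families fold differently. Of 72 tests of 18 lists and 4 measures, 3 passed an adjusted p of 0.05 in two-sided permutation tests, and the same number adjusted over the list alone. The 3 transcripts of let-7 group I had larger apical loops than other RNAs, 20.0 ± 1.73 nt (SD, n = 3) against 9.34 ± 3.95 nt (n = 473; exact permutation test, adjusted p = 0.00428), with each of the 3 above the other RNAs' mean. The list of the chromosome 19 cluster, a primate family expressed in placenta, had smaller apical loops, 7.03 ± 3.41 nt (n = 40) against 9.63 ± 4.02 nt (n = 436, permutation, adjusted p = 0.00252), and 32 of the 40 listed members analysed lay below the other RNAs' mean. Its mean hairpin reactivity, relative to each RNA's own scale, was also lower, 0.284 ± 0.0715 against 0.348 ± 0.0578 (permutation, adjusted p = 0.00072), in 30 of 40 members. These 40 genes lie on chromosome 19 between 53666679 and 53762430 (GRCh38.p14). The genes of mir-1283-1 and mir-1283-2 start within this span, at 53688481 and 53758232. They were not in the list and were counted among the other RNAs. In the 40 listed RNAs loops ranged from 3 nt in mir-516a-2 to 15 nt in mir-518e, and hairpin reactivity from 0.129 in mir-519e to 0.416 in mir-526b. With each name family counted once, the loop difference of the cluster was -2.04 nt (permutation, adjusted p = 0.895) and the reactivity difference -0.0451 (permutation, adjusted p = 0.0915). Neither loop result passed the threshold with short helices of the models opened. With helices of fewer than 4 stacked pairs next to the apical loop opened in all RNAs, the loop difference was 7.75 nt for let-7 group I (exact permutation test, adjusted p = 0.4) and -1.38 nt for the cluster (permutation, adjusted p = 0.765). With helices of fewer than 5 opened, the cluster's difference was 1.13 nt (permutation, adjusted p = 0.785), and the miR-17 family had larger opened loops, 29.4 nt (n = 7) against 16.7 nt (permutation, adjusted p = 0.0439). With helices of fewer than 6 opened, these were 39.7 nt (n = 6) and 20.4 nt (permutation, adjusted p = 0.0137).

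The other 69 tests did not pass, the lowest of their adjusted p-values being 0.61 (permutation). The 8 analysed members of the miR-10 family had loops of 12.4 ± 3.78 nt, from 4 nt in mir-99b to 16 nt in mir-10a (permutation p = 0.0371 before adjustment). Loops of the miR-30 family averaged 12.3 ± 4.76 nt (n = 6), from 3 nt in mir-30c-1 to 16 nt in mir-30e. The miR-29 family had 32 ± 3.56 stem pairs (n = 4), from 27 in mir-29a to 35 in mir-29b-2, against 36.7 ± 5.60 in other RNAs. The miR-9 and miR-124 transcripts of the nervous system had a hairpin reactivity of 0.296 ± 0.0294 (n = 6), each below the mean of other RNAs. The muscle transcripts (n = 8) had 34.9 ± 5.57 stem pairs and loops of 10.3 ± 3.92 nt, from 5 nt in mir-133b to 14 nt in mir-1-1. The miR-154 group of the chromosome 14 cluster had loops of 10.7 ± 2.15 nt (n = 26), from 5 nt in mir-376a-1 to 14 nt in mir-381. This group is only part of the cluster. Further analysed RNAs with genes within its span, such as mir-134, mir-299 and mir-380, were counted among the other RNAs. With stems ended at the first large internal loop, 5 tests passed, and the added ones were fewer stem pairs (28.1 against 33.7, permutation adjusted p = 0.0215) and higher hairpin reactivity (0.409 against 0.340, permutation adjusted p = 0.0133) in the miR-154 group. The miR-17, miR-19, miR-92, miR-15, miR-34, miR-181, miR-200 and miR-302 lists passed no test on the structures as modelled, with loops averaging 7.71, 8.00, 8.00, 9.71, 10.2, 12.2, 7.25 and 9.25 nt in that order.

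**Figure D4:**
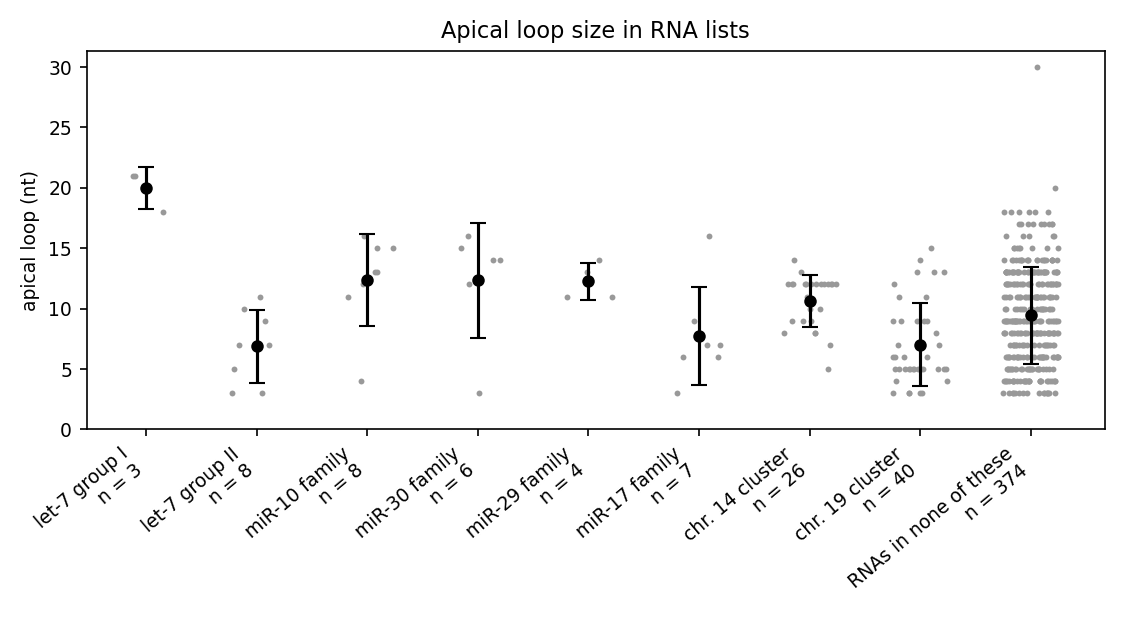
Apical loop size in nt, as modelled, (vertical axis) of the members of RNA lists (horizontal axis); grey points are RNAs and black points with bars the mean ± SD. The let-7 group I loops average 20.0 nt and those of the chromosome 19 cluster 7.03 nt.

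The let-7 family is divided by the 3′ overhang of its precursors into group I (let-7a-2, let-7c and let-7e) and group II, which is extended by a nucleotide before Dicer acts. Group I loops had 21 nt in let-7a-2 and let-7c and 18 nt in let-7e. The 8 analysed group II loops averaged 6.88 ± 3.04 nt (SD, n = 8), from 3 nt in let-7a-3 and let-7f-2 to 11 nt in mir-98, with 5 nt in let-7a-1 and 10 nt in let-7g. The difference of 13.1 nt was the largest of all 165 splits of the 11 RNAs (exact permutation test, p = 0.00606, adjusted p = 0.0303 over 5 measures). Without let-7a-1, and with helices of fewer than 4 stacked pairs next to the loop opened, it was 14.5 nt, the largest of all 120 splits (exact permutation test, p = 0.00833). With helices of fewer than 5 opened it was 7.95 nt (exact permutation test, p = 0.267), as the opened loop had 26 nt in let-7f-2 and 33 nt in let-7g. With helices of fewer than 6 opened it was -2.76 nt (exact permutation test, p = 0.742). Stem pairs (37.3 and 35.5), unpaired share of the stem (22.4% and 18.3%), hairpin reactivity (0.392 and 0.369) and area under the curve (0.872 and 0.855) had adjusted p-values of 0.773 to 0.855 in exact permutation tests. The stem mean of group II was lowered by the 3 pairs of let-7a-1, and without it was 40.1 pairs, above that of group I (exact permutation test, p = 0.433). The window at the mature let-7 end that had been planned for this comparison needs the sequence and was not run, and loop size was chosen in its place after the tables had been seen. The gene of let-7a-2 lies at 122146522 to 122146593 on chromosome 11, within the span of the non-coding gene MIR100HG (GRCh38.p14). That of let-7c lies at 16539828 to 16539911 on chromosome 21 within MIR99AHG, and that of let-7e at 51692786 to 51692864 on chromosome 19 within SPACA6 and the non-coding gene SPACA6-AS1. On the same assembly mir-21 lies at 59841266 to 59841337 on chromosome 17 within VMP1, and mir-155 at 25573980 to 25574044 on chromosome 21 within MIR155HG. Strand and exon were not part of the annotation table.

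On average, RNAs of the same list had slightly more similar reactivity profiles than RNAs of different lists, but not in every list. The lists are families or groups made by tissue, and the groups made by tissue were not tested as a set. The chromosome 14 and 19 clusters were left out of this comparison. Aligned on the middle of the apical loop, 252 pairs of RNAs within 14 lists had a mean Spearman correlation of 0.194 ± 0.152, against 0.157 ± 0.141 for 3403 pairs between lists (SD over pairs, 86 RNAs). With names shuffled among the RNAs the mean within lists was 0.160 (one-sided permutation test, p = 0.0001, the smallest that 10000 shuffles can give). In the 11 lists that are families, without the brain, muscle and miR-302 lists, it was 0.184 ± 0.149 (181 pairs of 64 RNAs) against 0.142 with names shuffled (one-sided permutation test, p = 0.0004), and 3 of these lists lay at or below the mean of random sets. No single list passed after adjustment. Among the 14 lists, the miR-15, miR-17, miR-92, miR-200 and miR-302 lists lay below the mean of random sets of their size. The highest means were 0.296 for miR-9 and miR-124 and 0.269 for the miR-10 family (adjusted p = 0.164 for both, permutation), and the lowest were 0.0670 for miR-200 and 0.0832 for miR-15. The highest pair within the let-7 list was let-7a-2 and let-7e (0.590), within the miR-10 list mir-10b and mir-125b-1 (0.562), and within the miR-34 list mir-34a and mir-449a (0.494). The share of identical bases between RNAs was not computed because the tables hold no sequence.

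The 3 control RNAs have reactivity but no structure in the tables. In yeast tRNA-Asp the 3 highest values, 4.48, 4.28 and 2.79, lay side by side at positions 32, 33 and 34 of 75, the middle of the molecule, where a tRNA has its anticodon loop. In domain II of the hepatitis C virus IRES, 11 of 95 nucleotides exceeded 0.85, with the highest at position 7 (2.14). In U1 snRNA, 18 of 125 nucleotides did, with a highest value of 1.95.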

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

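The tests of another RNA's row, of a shift and of opened helices were chosen after the results had been seen. So were those of the stem pair share in the chromosome 19 cluster and of other splits of the let-7 RNAs.

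The RNAs with reactivity but no structure, mir-873 and mir-941-4, carry signal that no comparison used, with 19 and 18 nucleotides above 0.85. Over positions 54 to 66, where most apical loops lie, mir-873 averaged 0.979 and mir-941-4 0.577, against 0.85 ± 0.284 (SD, n = 476) in the structured RNAs. Their Spearman correlations with the mean profile were 0.380 and 0.311, against a median of 0.390 for structured RNAs. In mir-941-4, 49 of 125 nucleotides stood at exactly 0.

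In 16 RNAs the area under the curve was below 0.6, so that reactivity hardly ranked unpaired above paired nucleotides; they include mir-210, mir-196b, mir-29a, mir-15b and mir-143, named after their values were seen. A row exchanged with that of another RNA of the table after the modelling is argued against. The best structure of any other RNA gave a median of 0.663, below the 0.737 that is the 25th percentile of own structures. A shift of up to 5 nt that arose after the modelling is argued against in the same way, with a median of 0.598 at the best shift. The structures were modelled with these reactivities, so an earlier exchange or shift would be built into them, and these values do not speak on it. Few informative reads may play a part, since 33.8% ± 16.4 (SD, n = 16) of their nucleotides stood at exactly 0 against 23.1% ± 8.77 (n = 460), a difference of 10.7 percentage points (permutation, p = 2e-05). The share of zeros was low in some of them, at 3.20% in mir-196b and 8.80% in mir-143, and no biological explanation was tested.

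The chromosome 19 cluster had smaller apical loops and lower hairpin reactivity than other RNAs. Whether scaling of each RNA to its own percentile lowers the reactivity stays open: the rank of hairpin nucleotides within the RNA was lower (45.3 ± 3.66 against 48.5 ± 2.99, difference -3.23; permutation, p = 1e-05, the smallest it can give), but a more reactive 3′ flank would lower that rank too. Stem pairs were also taken as a percent of stem pair plus apical loop reactivity, which scaling cannot change while the modelled pairs stay fixed. This percent differed by -4.88 (12 ± 4.95 against 16.8 ± 10.7, permutation, p = 0.00644), and was below the other RNAs' mean in 35 of 40. With each family counted once it differed by -4.94 at p = 0.0605 (permutation). The pairs were modelled with these reactivities, so scaling or flank could still act through which nucleotides were modelled as stem or loop. Sharing of most reads between near-identical copies would make profiles alike, but the median of the best correlation with another member was 0.564, and mir-516a-1 with mir-516a-2 had the highest at 0.708. Profiles were aligned on the middle of the modelled loop, so copies with differently modelled loops could be compared out of register. Sharing of only some reads stays open. That related RNAs were counted as independent stays open: with 16 families against 339 the loop difference was -2.04 nt (7.51 ± 2.95 against 9.55 ± 3.76; permutation p = 0.0328, and 0.895 after adjustment over the lists) and the reactivity difference -0.0451 (0.301 against 0.346; permutation p = 0.00161, and 0.0915 after adjustment), so the bound set in advance, which had no adjustment, was too mild to decide, and common descent of the cluster is a candidate explanation that was not tested.

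The apical loop of let-7 group I was larger than that of group II by 13.1 nt. Whether it is a choice of the folding model stays open. Mean reactivity over construct positions 50 to 70 was 0.985 ± 0.183 (SD, n = 3) in group I and 0.718 ± 0.136 (n = 8) in group II, a difference of 0.267 (exact permutation test, p = 0.0242), but that window is the modelled loop of let-7a-2, so the test decides nothing, and let-7b (0.902) and let-7i (0.892) lay above let-7e (0.815). A few modelled closing pairs could carry the difference: without let-7a-1 it was 14.5 nt with helices of fewer than 4 stacked pairs opened and 7.95 nt with those of fewer than 5 opened (exact permutation tests, p = 0.00833 and 0.267), and 26.8% to 38.5% of the apical segment was unpaired in 7 group II RNAs against 0% to 3.70% in group I. The count of splits, 1 of 165 with the largest of the others at 9.92 nt, is the permutation already given for a measure picked because it stood out, so it does not speak on chance, and no biological explanation was tested.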

How the results depend on the processing

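Ending the stem at a large internal loop, leaving out let-7a-1 or zeros, counting families once in the lists, opening helices, the family lists alone, and the settings of the arm windows, correlations, area under the curve and let-7 loop (apart from leaving out each member) were chosen after the tables had been seen. So were the middle-nucleotide hairpin for elements, the removal of isolated pairs for elements, helix ends and unpaired against paired, and the median, capping and ends left out for arm reactivity. Of 288 values under alternatives, without the filter that removed no RNA, 269 were counted as unchanged. Tested values had to keep their side of the threshold, and their direction where either value passed it. Counts had to lie within 1.5 times the reported count, and untested means and medians within the SD between RNAs. Some values could not change. Ending the stem leaves apical loop sizes as they are, and opening helices leaves hairpin reactivity as it is, so the tally overstates stability. The element pairs that passed fell from 15 to 14 with the stem ended at a large internal loop. Unpaired minus paired reactivity ranged from 0.410 (median of nucleotides) to 0.585 (ends left out) over 7 alternatives. Internal loops minus 3′ flank was reversed with the ends left out (-0.151), and the cause was not tested. With the stem ended at a large internal loop it was -0.00922 (permutation adjusted p = 0.618), so the parts were not told apart. That setting by definition counts the large loop, and unpaired nucleotides beyond it, as flank. With zeros left out the reactivity difference between arms was no longer past the threshold (0.0420, permutation adjusted p = 0.0515). With the stem ended at a large internal loop 5 list tests passed, and stem length no longer went with loop size (r = -0.0228). With each family counted once 0 list tests passed, the chromosome 19 cluster differing by -2.04 nt and -0.0451; the cluster then counts 16 families in place of 40 RNAs. Loop size against loop reactivity passed the threshold with the hairpin that holds the middle nucleotide (r = -0.0947, permutation adjusted p = 0.0377) and without let-7a-1 (r = -0.0921, permutation adjusted p = 0.0445). With helices of fewer than 4, 5 or 6 stacked pairs next to the loop opened, the loop difference of let-7 group I from other RNAs was 7.75, 4.83 and 0.982 nt (exact permutation adjusted p = 0.4 to 0.936) and that of the chromosome 19 cluster -1.38, 1.13 and -1.25 nt (permutation adjusted p = 0.765 to 0.851), with 1, 2 and 2 list tests passed. Group I minus group II was 14.5 nt below 4 pairs, 7.95 nt below 5 and reversed to -2.76 nt below 6. Leaving out each let-7 RNA in turn gave loop differences of 12.6 to 14.1 nt, with exact permutation p-values up to 0.0222. The filter on RNAs with 95% of values removed none and tests nothing, and families could not be counted once for let-7 group I, which is 1 family. No paired analysis was possible because the labels share replicate numbers but the tables hold no value per replicate, so no replicate was left out or used as a block. Sequence-only folding and every alternative that needs it were not run. Depth limits which zeros can be told from low reactivity, and it is unknown.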

Other observations

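The apical loop sizes, the strands next to loops and the parts of the chromosome 19 cluster were looked at after the results had been seen.

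Apical loops of 9 nt were found in 48 RNAs, of 10 nt in 22, of 12 and 13 nt in 49 and 50, and of 15 nt in 12. Loops of 5 nt were found in 41 RNAs, of which 13 are in the list of the chromosome 19 cluster, and outside that list loops of 4, 5 and 6 nt were found in 32, 28 and 35 RNAs. By part of the RNA, and relative to each RNA's own scale, the cluster differed in its stem pairs and its 3′ flank. Stem pairs had 0.136 ± 0.0485 (SD, n = 40) against 0.179 ± 0.0675 (n = 436) in other RNAs (permutation, adjusted p = 0.00042), and the 3′ flank was higher, 0.730 ± 0.328 (n = 40) against 0.427 ± 0.271 (n = 413; permutation, adjusted p = 6e-05). Apical loops had 1.05 ± 0.281 and 1.03 ± 0.401 (permutation, adjusted p = 0.775). The comparisons by part count the related RNAs of the cluster as independent, and were not repeated with each family counted once. A more reactive flank lowers the scaled values of the other parts, so these are relative and not absolute levels.

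Paired nucleotides on the 5′ side of unpaired stretches reacted more than those on the 3′ side. In the 7 pairs next to the apical loop, the 5′ strand had 0.245 ± 0.159 and the 3′ strand 0.190 ± 0.140 (SD, n = 476), with the 5′ strand higher in 308 RNAs (sign-flip permutation test, adjusted p = 5e-05). At the closing pair itself the values were 0.449 and 0.349 (adjusted p = 0.0007, permutation). Next to internal loops the 5′ side had 0.232 and the 3′ side 0.201 (n = 474; permutation, adjusted p = 0.000275), and next to bulges 0.345 and 0.291 (n = 390; permutation, adjusted p = 0.00635). In pairs stacked on both sides, which border no unpaired stretch, the difference between the 5′ and the 3′ strand was 0.00797 (permutation, adjusted p = 0.019). The pairs were modelled with these reactivities, so these differences describe the models.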
